A study of Mus musculus with 8 samples.

How the data were processed

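Gene expression was measured on 1-colour arrays in 8 samples of virus-specific mouse CD8 T cells, 4 from wild-type littermates (WT) and 4 from mice with a conditional deletion of Blimp-1 (CKO). Per the labels' protocols, mice received 200000 plaque-forming units of the Armstrong strain of lymphocytic choriomeningitis virus. Spleen cells were stained 8 days later for CD8 and for binding of class I tetramers carrying viral peptides of the glycoprotein and the nucleoprotein, and were sorted by flow cytometry. RNA was extracted, amplified and turned into biotinylated cRNA with an Illumina kit, per the labels' protocols.

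The deposited table holds 1 log2 value per probe and array for 24048 probes. The scanner, background correction, normalization method and probe filter are not given in the sources used here. The values themselves show that the authors normalized between arrays: sorted columns differed by at most 0.165 log2. Also, 2 raised to the value was a whole multiple of 1/80 for 100% of values. The tolerance was a small fraction of a step of this 1/80 grid, or a relative 5e-07 where that was larger. For the brightest values it spans the whole step, so these pass by construction. Such a grid arises when values with 1 decimal are averaged over 8 arrays, as quantile normalization does. The lowest value per array was 5.33 or 5.34 and the highest 15.15, and every array had a median of 6.15. Values were not centred per probe, and their direction is signal, so a higher value means more RNA. Whether background was subtracted is unknown. A floor above 5 in log2 units compresses the fold changes of dim probes, so these are understated. Detection p-values were not used here. Between 0.952% and 1.31% of probes had no value on an array, and 66 probes had none on any array. For arrays, the number of samples limits the precision.

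Gene names came from the platform annotation that GEO pairs with the probes: 19397 probes carried 1 gene symbol that was used, 0 carried several, and 4651 were left unnamed. The 18S ribosomal RNA control probe was listed under an unrelated gene and its name was dropped, a choice made after the table was seen. Older symbols of list members were matched through synonyms in a mouse gene table of assembly GRCm38.p6, which served also to find the neighbours of Prdm1 and the genes on its chromosome. The positions of the probes are not given in the sources used here, and no coordinates are reported.

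Samples were grouped by genotype as labelled. The design text names 4 independent samples per group but does not say that each came from a separate animal, so p-values measure the spread between these samples, part of which may be technical. The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The deposited values were used without further normalization. A probe was tested if its mean over the 8 arrays lay above the median of all probes, 6.12, which left 11991 probes with 5 missing values, 9955 of them named. Each of 8095 genes was represented by its brightest probe. CKO and WT were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. All differences are CKO minus WT in log2 units. SE is the moderated standard error, and intervals are at 95%.

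The 21 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Genes with a missing value were left out of these list tests, a choice made once the table had been seen. List members without a tested probe were not analysed here. Named genes were Prdm1, the 15 genes with the largest difference in each direction among those past the threshold whose groups did not overlap, and up to 4 members per list with the largest difference past the threshold. Where no member of a list passed, the 2 with the smallest p are given. Genes outside this rule are said to have been chosen after their values were seen.

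Both groups carry replicate numbers 1 to 4. Deviations from the group means of same-numbered samples correlated at 0.326, 0.467, 0.181 and 0.225, across probes, which are not independent replicates. All 4 lay above the limit of 0.1 set for treating the numbers as pairs, so a fit with the number as a block is given where it changed a call. WT3 with CKO4 and WT4 with CKO3 correlated as highly, at 0.255 and 0.264, so the numbers do not separate samples 3 and 4. The Y-linked genes Eif2s3y and Kdm5d were bright in WT1 and CKO1 only. These 2 samples therefore held cells from males, which the other samples did not show. Each group held 1 such sample under the same number, so the fit with the number as a block also takes up this difference. No fit left out only the samples numbered 1. No 2 arrays held identical values.

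Alternatives were repeated quantile normalization, median centring, no filter on dim probes (with at least 6 values required), the upper quartile of probes, log2 after adding 50 to the linear value, the replicate block, array weights, eBayes with trend and robust settings, an adjusted p under 0.1, a fold of at least 1.5, the mean of a gene's probes, and leaving out each sample. Cyclic loess, leaving out both samples numbered 2, and fits on samples numbered 1 and 2 or 3 and 4 alone were added after the data were seen.

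The fit was tested on simulated data for 4 against 4 arrays, with the means and spreads of 11986 probes and 200 changed probes in each of 10 runs. It recovered 40% of changes of 0.5 log2, 91.2% of changes of 1, 97% of changes of 1.5 and 99.2% of changes of 2, and 5.48% of the calls were false. A list shifted by 0.5 was called in 10 of 10 runs, and 0.5% of unshifted lists were called. The simulated noise was independent between probes. These rates therefore do not cover correlation between genes or deviations shared by samples, and false calls of lists may be more frequent in the real data.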

Results

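Blimp-1, the transcriptional repressor encoded by Prdm1, was deleted in CD8 T cells with a Cre recombinase expressed under granzyme B control, and effector cells from these CKO mice were compared with those of WT littermates. The question the design poses is which transcripts of virus-specific effector cells differ at day 8 of an acute infection when Blimp-1 is missing. Each group held 4 sorted samples, with 1 array each. Values are log2 signals on a scale running from 5.33 to 15.15, given as mean ± SD with n = 4 per group. Arrays correlated at 0.972 to 0.993 within a group and 0.958 to 0.981 between groups across tested probes. The first principal component held 38.7% of the variance and placed all WT samples below all CKO samples. The second held 24.3% and set apart WT2 at -16.0 and CKO2 at -27.4. These 2 samples also had the lowest 18S ribosomal RNA signal, 11.2 and 10.8, against 12.5 to 13.0 in the other samples.

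Prdm1, the targeted gene, was measured by 2 probes that moved in opposite directions. On the first, signal fell from 7.78 ± 0.27 in WT to 6.50 ± 0.15 in CKO, a difference of -1.28 (SE 0.14, limma adjusted p = 0.00121) or 2.43-fold. On the other, signal rose from 5.81 ± 0.22 to 9.01 ± 0.29, a difference of 3.20 (SE 0.16, adjusted p = 4.43e-06) or 9.20-fold. In no sample did the values of the groups overlap on either probe. The WT mean of the second probe was above 15.2% of all probes, close to the floor, so its rise is understated. The CKO mean of the first probe was above 63.4% of all probes but near the array median of 6.15, so its fall may be understated too. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside that part would not check the labels. The brighter probe represents Prdm1 in the gene counts, where it therefore stands among the genes that were higher. With samples numbered 1 and 2 alone, a fit added after the data were seen, the fall was -1.18 and no longer passed the threshold (adjusted p = 0.116).

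**Figure D1:**
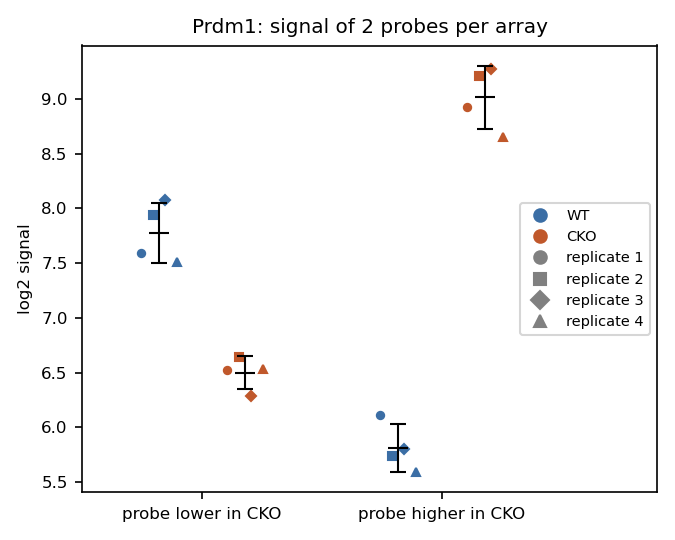
Log2 signal of the 2 Prdm1 probes in each array, WT in blue and CKO in orange, with a marker shape per replicate number and black bars for mean ± SD. The first probe fell from 7.78 to 6.50 and the second rose from 5.81 to 9.01, with no overlap between groups.

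The list of central memory and memory precursor transcripts was higher in CKO cells and that of terminal effector transcripts lower (camera adjusted p = 8.30e-09 and 2.97e-10). Ccr7, the chemokine receptor that guides T cells into lymph nodes, rose from 7.21 ± 0.09 to 10.95 ± 0.25, or 13.4-fold (adjusted p = 4.51e-07). Nsg2, a vesicle protein known mostly from neurons, rose 11.7-fold (adjusted p = 7.53e-07), and Xcl1, the chemokine lymphotactin, rose 8.47-fold, from 9.14 ± 0.27 to 12.23 ± 1.01 (adjusted p = 0.00252). S1pr5, a sphingosine-1-phosphate receptor, fell 7.84-fold, from 10.22 ± 0.41 to 7.25 ± 0.74 (adjusted p = 0.00126). Cx3cr1, the fractalkine receptor, fell 6.49-fold, from 11.34 ± 0.40 to 8.64 ± 0.64 (adjusted p = 0.00121). Other large rises were those of Ccr6, a chemokine receptor, at 2.51 log2, Mgarp at 2.48, Cxcl10, a chemokine induced by interferon, at 2.14, Dkk3 at 1.79, Rgs10 at 1.78, Cphx1 at 1.72, Adk, adenosine kinase, at 1.71, Tnfrsf26 at 1.70, Tnfrsf4, the costimulatory receptor OX40, at 1.67, and Kit, the stem cell factor receptor, at 1.62, with adjusted p from 0.000245 to 0.0203. Large falls were also those of Galnt10 at -1.88, Irak3 at -1.87, Sema4a at -1.82, Esm1 at -1.64, Hid1 at -1.61, Gpx8 at -1.57, Ly6f at -1.52 and Pxylp1 at -1.50, with adjusted p from 0.000288 to 0.0132. The WT means of Ccr6, Mgarp, Cxcl10, Dkk3, Cphx1 and Kit were 6.15, 5.98, 6.17, 6.34, 5.98 and 6.18, and the CKO mean of Gpx8 was 5.93, all near the floor, so these differences understate the change and carry no order. Rgs10 lost its call without CKO3 (adjusted p = 0.0719) or CKO4 (0.058).

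In all, 383 genes were higher and 246 lower in CKO, 7.77% of 8095 genes tested, of which 66 were higher and 36 lower by at least 2-fold. Groups did not overlap in 612 of these 629 genes, and in 15.7% of all genes tested, where chance gives 2.86%. Among probes, 495 were higher and 305 lower, including 80 and 40 probes without a gene name. With the replicate number as a block, 556 genes were higher and 461 lower, and 626 of the 629 remained. The counts depended on single samples: 189 higher and 102 lower without CKO3, 253 and 138 without CKO4, 230 and 135 without WT1, and 249 and 167 without WT3. Of 119 called genes with several tested probes, 16 had a probe of opposite sign. Only 24 genes had 2 or more probes past the threshold, and in 1 of these, Prdm1, such probes were opposite in direction.

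**Figure D2:**
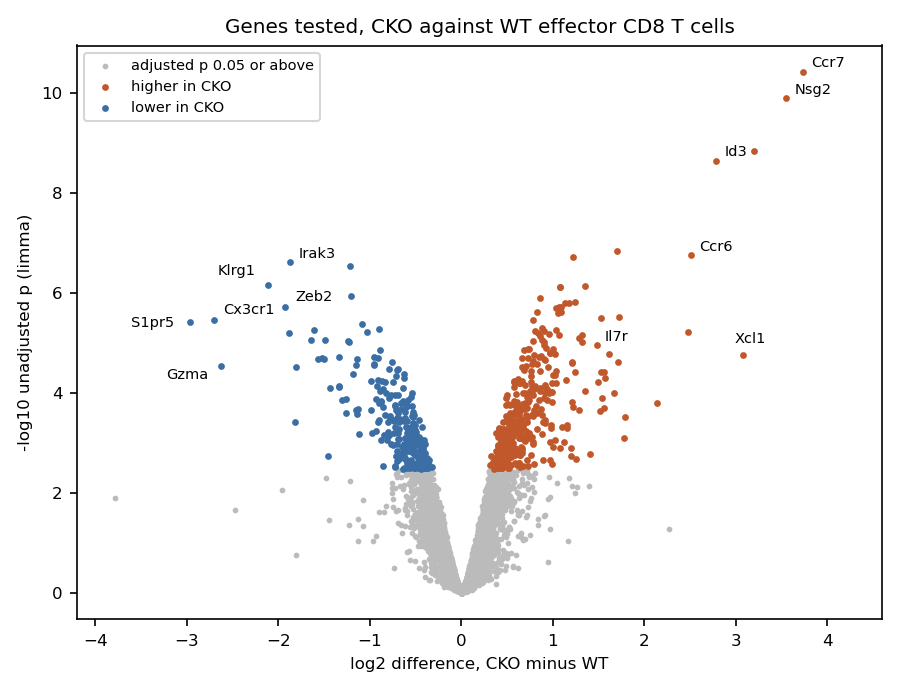
Log2 difference (CKO minus WT) against -log10 unadjusted limma p for the 8095 genes tested, with orange for the 383 genes that were higher, blue for the 246 that were lower, and grey for the rest. Ccr7 lies farthest right among called genes at 3.74 and S1pr5 farthest left at -2.97.

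Transcripts of central memory cells and memory precursors rose as a group. Of 16 members measured, 9 rose, none fell and 7 did not pass over all genes; adjusted over the list alone, 10 rose and 1 fell. The list median was 0.52 log2 (camera adjusted p = 8.30e-09; adjusted p = 0.0122 with an estimated correlation). Besides Ccr7, Id3, an inhibitor of DNA-binding proteins linked to memory precursors, rose 6.91-fold from 6.98 ± 0.27 to 9.77 ± 0.18 (adjusted p = 4.89e-06). Il7r, the interleukin 7 receptor that sustains memory cells, rose 2.79-fold from 10.33 ± 0.29 to 11.80 ± 0.33 (adjusted p = 0.00194). Slamf6, a surface receptor of less differentiated T cells, rose 2.32-fold (adjusted p = 0.00782). Bcl2, which protects cells from apoptosis, rose 1.99-fold (SE 0.17 log2, adjusted p = 0.00794).

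Transcripts of terminal effector cells fell as a group. Of 20 members measured, 11 fell, none rose and 9 did not pass over all genes; adjusted over the list alone, 14 fell and 1 rose. The list median was -0.71 (camera adjusted p = 2.97e-10; adjusted p = 0.0484 with an estimated correlation). S1pr5 and Cx3cr1 fell most. Klrg1, a receptor that marks terminally differentiated effector cells, fell 4.34-fold from 11.95 ± 0.11 to 9.83 ± 0.46 (adjusted p = 0.000577). Zeb2, a transcription factor of terminal effector cells, fell 3.80-fold (SE 0.20 log2, adjusted p = 0.000874). Klrb1c, a natural killer cell receptor gene chosen after its values were seen, was at 9.95, 9.91, 6.72 and 8.04 in WT1 to WT4 and between 6.63 and 6.77 in CKO (adjusted p = 0.0885).

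**Figure D3:**
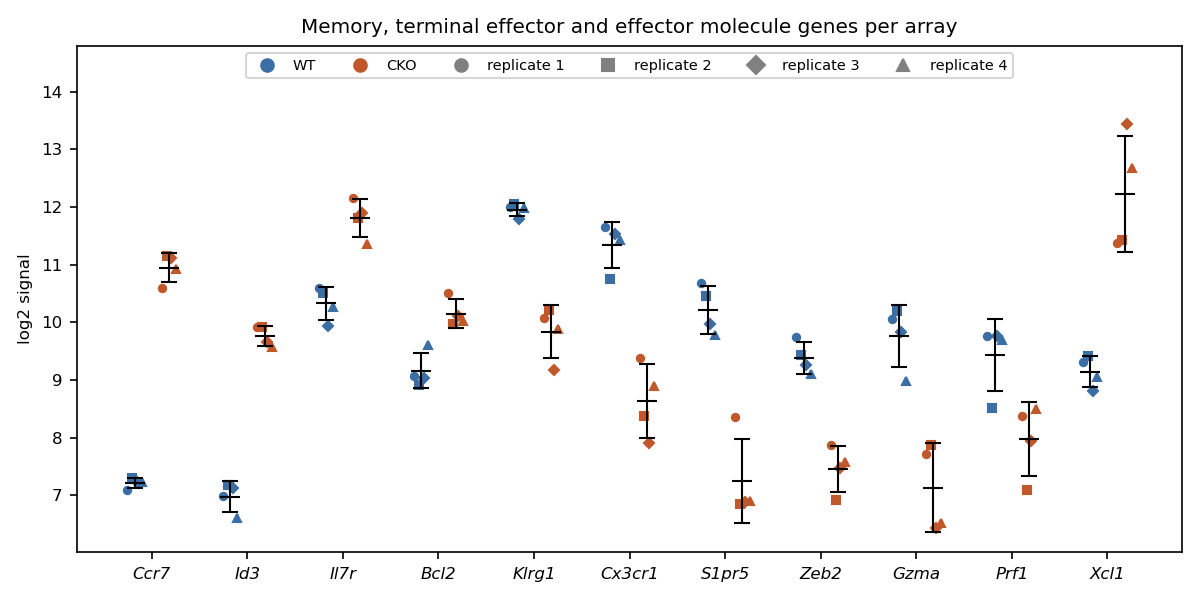
Log2 signal per array of 11 memory, terminal effector and effector molecule genes, WT in blue and CKO in orange, with a marker shape per replicate number and black bars for mean ± SD. Ccr7, Id3, Il7r, Bcl2 and Xcl1 were higher in CKO, and Klrg1, Cx3cr1, S1pr5, Zeb2, Gzma and Prf1 were lower.

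Cytotoxic effector molecules and cytokines went both ways. Of 17 members measured, 4 rose and 6 fell over all genes, with 4 and 7 adjusted over the list alone, and the list did not shift (median -0.27, camera adjusted p = 0.131). The 4 that rose were Xcl1, given above, and Gzmm, Tnf and Lamp1, which were chosen after their values were seen. Gzmm, granzyme M, rose 2.32-fold, Tnf 1.67-fold and Lamp1 1.49-fold (limma adjusted p = 0.00887, 0.0179 and 0.00772). Gzma, the protease granzyme A, fell 6.19-fold from 9.76 ± 0.54 to 7.13 ± 0.77 (adjusted p = 0.00319). Fasl, which triggers death of target cells, fell 2.80-fold (adjusted p = 0.0017). Prf1, the pore-forming protein perforin, fell 2.75-fold (adjusted p = 0.0343), although WT2 lay at 8.51 and the nearest WT sample at 9.70. The call for Prf1 was lost without WT1, WT3, WT4 or CKO3 (adjusted p = 0.103, 0.0968, 0.0872 and 0.1). The Gzmb probe, for granzyme B, was dim in both groups, at 5.78 to 6.12 in WT and 5.62 to 6.17 in CKO, and was below the filter. Values this near the floor cannot tell an absent transcript from a probe that does not report it. The list passed without CKO4 (adjusted p = 0.0269, lower), and in samples 1 and 2 alone (adjusted p = 0.00562, lower).

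Among 6 inhibitory receptors measured, 3 rose and 1 fell over all genes, with 5 and 1 adjusted over the list alone (median 0.74, camera adjusted p = 0.0213; adjusted p = 0.373 with an estimated correlation). The list median relative to the WT mean was 1.17 in CKO3 and 1.01 in CKO4, the samples with the higher interferon-stimulated list, but 0.45 in CKO1 and 0.33 in CKO2, against -0.27 to 0.33 in WT samples. Ctla4, which restrains costimulation, rose 2.29-fold although the groups overlapped (adjusted p = 0.0268). Cd160 rose 1.84-fold (adjusted p = 0.0179) and Btla 1.73-fold (adjusted p = 0.0241), whereas Havcr2, which encodes Tim-3, fell 2.20-fold (adjusted p = 0.00965). With 1 sample left out the rises kept their direction, at 1.00 to 1.45 log2 for Ctla4, 0.69 to 0.96 for Btla and 0.75 to 1.04 for Cd160, but some calls were lost: for Ctla4 without WT1, WT2, WT3, CKO3 or CKO4 (adjusted p = 0.0605 to 0.0912), for Btla without WT1, WT2, CKO1, CKO3 or CKO4 (0.054 to 0.0843), and for Cd160 without WT1, WT4, CKO3 or CKO4 (0.0509 to 0.0613). Among 10 natural killer cell receptors, which effector CD8 cells share in part, 1 rose and 1 fell over all genes, with 1 and 4 adjusted over the list alone (median -0.12, camera adjusted p = 0.169). The member that fell, Klrd1, fell by 0.64 log2 (adjusted p = 0.00764). That list passed without WT2 (adjusted p = 0.0496, lower) or CKO4 (0.0328, lower).

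Receptors for migration moved in opposite directions. Of 16 measured, 3 rose and 6 fell over all genes, with 4 and 6 adjusted over the list alone (median -0.07, camera adjusted p = 0.436). Ccr7 and Ccr6 rose, whereas S1pr5, Cx3cr1 and Cxcr6, the receptor for Cxcl16, fell, the last 3.51-fold (adjusted p = 0.00325). Among 27 cytokine receptor and signalling genes, 3 rose and 3 fell, with 4 and 4 adjusted over the list alone. Median and mean were -0.01 and -0.03 while camera gave the direction as higher (adjusted p = 0.886). Cish and Socs2, feedback inhibitors of cytokine signalling, fell 2.52-fold and 2.23-fold (adjusted p = 0.0026 and 0.0098). Socs3, another such inhibitor on the list, chosen after its values were seen, rose by 0.926 log2 (adjusted p = 0.00215). Il18rap, a chain of the interleukin 18 receptor, fell 2.39-fold (adjusted p = 0.00728). Among 7 genes known from other work as Blimp-1 targets, 2 rose and 2 fell over all genes and adjusted over the list alone (median 0.02, camera adjusted p = 0.436; fry adjusted p = 0.012). These were Id3 and the repressor Bcl6, up 2.11-fold (adjusted p = 0.0268), and Tbx21, which encodes T-bet, down 2.21-fold (adjusted p = 0.0106), and Ifng, interferon gamma, down 1.65-fold with overlapping groups (adjusted p = 0.0455). The Bcl6 call was lost without WT3, WT4, CKO3 or CKO4 (adjusted p = 0.0665 to 0.0772), and that of Ifng without any 1 sample other than CKO4 (0.0518 to 0.135).

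Cell cycle and cell death genes did not shift. None of 26 cell cycle genes passed, over all genes or adjusted over the list alone (median -0.02, camera adjusted p = 0.849). The members nearest the threshold were Ccna2, cyclin A2, at -0.61 (adjusted p = 0.106), and Mcm6, a replication helicase subunit, at 0.25 (adjusted p = 0.182). The direction of the list was unstable: it was lower without WT2 (adjusted p = 0.0433) and in samples 3 and 4 alone (0.000227), and higher in samples 1 and 2 alone (0.00562). Of 16 cell death regulators, Bcl2 rose and Fasl fell over all genes and adjusted over the list alone (median -0.05, camera adjusted p = 0.886).

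Enzymes of glycolysis were higher. Of 14 measured, 5 rose and 1 fell over all genes, with 9 and 1 adjusted over the list alone (median 0.43, camera adjusted p = 3.38e-05; adjusted p = 0.305 with an estimated correlation). Relative to the WT mean, the list median was 0.68 in CKO3 and 0.58 in CKO4, and smaller in CKO1 and CKO2, at 0.26 and 0.34. WT samples were at 0.02 to 0.07. Tpi1, triosephosphate isomerase, rose 2.55-fold (adjusted p = 0.00601), Pgam1, phosphoglycerate mutase, 2.00-fold (adjusted p = 0.00401), Pkm, pyruvate kinase, 1.82-fold (adjusted p = 0.00258), and Pgk1, phosphoglycerate kinase, 1.75-fold (adjusted p = 0.00558). Of 19 genes of oxidative phosphorylation and fatty acid oxidation, 1 rose, with 4 adjusted over the list alone (median 0.14, camera adjusted p = 0.0186; adjusted p = 0.278 with an estimated correlation). That gene was Uqcrc2, a subunit of respiratory complex III, up 1.31-fold (adjusted p = 0.0378), a call lost without any 1 sample other than CKO2 (adjusted p = 0.0705 to 0.135). Of 28 cytosolic ribosome genes, 4 rose and none fell, with 7 and 1 adjusted over the list alone (median 0.09, camera adjusted p = 0.0213; adjusted p = 0.273 with an estimated correlation). Rps24 rose 1.82-fold, Rplp0 1.74-fold, Rpl22 1.67-fold and Rpl12 1.33-fold (adjusted p = 0.00157, 0.00143, 0.0205 and 0.0174). Rpl22 lost its call without WT1, WT3, WT4 or CKO3 (adjusted p = 0.0573 to 0.0678) and Rpl12 without WT1 or CKO3 (0.0554 and 0.0665). With the mean of its probes in place of the brightest, Rplp0 did not pass (adjusted p = 0.217).

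Of 13 genes of CD8 identity and T cell receptor signalling, 2 fell and none rose, with 5 lower adjusted over the list alone (median -0.06, camera adjusted p = 0.0444; adjusted p = 0.273 with an estimated correlation). Cd2, an adhesion receptor, fell by 0.54 log2 (adjusted p = 0.00857) and Thy1, a surface glycoprotein of T cells, by 0.46 (adjusted p = 0.0326), a call lost without any 1 sample other than CKO2 (adjusted p = 0.0602 to 0.117). The list call was lost with the replicate block (adjusted p = 0.0799) and without WT1, WT3, WT4, CKO1 or CKO2 (0.0515 to 0.115). Of 11 immediate early and stress genes, 2 rose, with 3 adjusted over the list alone (median 0.02, camera adjusted p = 0.205). These were Egr2, up 2.65-fold (adjusted p = 0.0322), and Fosb, up 1.99-fold (adjusted p = 0.0441), both transcription factors induced by stimulation. The WT mean of Fosb was 5.97, near the floor, so its rise is understated. With 50 added to the linear value its call was lost, at 0.65 log2 (limma adjusted p = 0.0591). With trend and robust settings both calls were lost (limma adjusted p = 0.0613 each). With 1 sample left out, Egr2 passed only without CKO1 or CKO2 (adjusted p = 0.0662 to 0.0882 otherwise), and Fosb only without CKO1 (0.0693 to 0.141 otherwise). That list passed without CKO1 (adjusted p = 0.0351, higher).

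As a list, interferon-stimulated genes were higher in 2 of the 4 CKO samples. Of 12 measured, 2 rose, with 2 adjusted over the list alone (median 0.45, camera adjusted p = 0.0132; adjusted p = 0.469 with an estimated correlation). The list median relative to the WT mean was 0.80 in CKO3 and 0.98 in CKO4, but -0.08 in CKO1, -0.12 in CKO2 and -0.14 to 0.10 in WT samples. Without CKO4 the call was lost (adjusted p = 0.0881). Usp18, which dampens interferon signalling, rose 2.95-fold (adjusted p = 0.00936), and Ly6e, an interferon-induced surface protein, 1.35-fold (adjusted p = 0.0488). With 1 sample left out, Ly6e passed only without WT4 or CKO1 (adjusted p = 0.0762 to 0.148 otherwise). Lyz2, a macrophage transcript chosen after its values were seen, was at 6.56, 6.98, 8.47 and 10.3 in CKO1 to CKO4. In WT1 to WT4 it was at 6.45, 6.73, 8.87 and 8.75. Lyz2 was thus higher in samples numbered 3 and 4 of both groups, while the interferon-stimulated list was higher in those of CKO only.

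Markers of other cell types were measured as well, since a sort can let such cells through. None of 8 B cell markers passed over all genes or over the list alone (median -0.27, camera adjusted p = 0.241), with Cd79a at -0.54 (adjusted p = 0.123) and Cd79b at -0.40 (adjusted p = 0.218). That list passed without CKO4 (adjusted p = 0.0299, lower). None of 11 macrophage and dendritic cell markers passed either (median 0.08, camera adjusted p = 0.516), with Ctss at 0.69 (adjusted p = 0.0766) and Cst3 at -0.10 (adjusted p = 0.674), and the list median of CKO4 was 1.31. Among 8 neutrophil markers, 2 fell, over all genes and adjusted over the list alone (median -0.45, camera adjusted p = 0.0236; adjusted p = 0.416 with an estimated correlation). These were Camp, an antimicrobial peptide, at -0.79 (adjusted p = 0.00345), and Ltf, lactoferrin, at -0.56 (adjusted p = 0.0455). Ltf lost its call without WT3, WT4, CKO2, CKO3 or CKO4 (adjusted p = 0.0697 to 0.136), and the list without WT3 or WT4 (0.0925 and 0.0644). Of 4 CD4 T cell markers, Tnfrsf4 and Il21 rose, with 3 higher and 1 lower adjusted over the list alone (median 0.51, camera adjusted p = 0.0444; adjusted p = 0.305 with an estimated correlation). The list call was lost with the replicate block (adjusted p = 0.0546) and without WT1, WT3 or WT4 (0.0683, 0.0588 and 0.0919), and that of Il21, a cytokine, at 0.68 (adjusted p = 0.0152), without WT1 (0.0519). The Cd4 probe itself was below the filter, at 5.94 ± 0.09 in WT and 5.85 ± 0.06 in CKO.

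Red blood cell transcripts were uneven between samples. None of 7 erythroid markers passed singly, over all genes or adjusted over the list alone, while the list was lower (median -0.96, camera adjusted p = 0.0444; adjusted p = 0.486 with an estimated correlation). Hba-a1, alpha globin, was at 13.3, 13.7, 12.3 and 12.1 in WT1 to WT4 and at 13.7, 8.29, 6.60 and 7.67 in CKO1 to CKO4. Its difference was -3.78 (SE 1.25, adjusted p = 0.109), and it passed with the replicate block (adjusted p = 0.025) and without CKO1 (adjusted p = 0.000855). Slc4a1, the anion exchanger of red cells, was at -1.13 (adjusted p = 0.341). The list call was lost without WT1, WT2, WT3, CKO2, CKO3 or CKO4 (adjusted p = 0.0616 to 0.194).

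**Figure D4:**
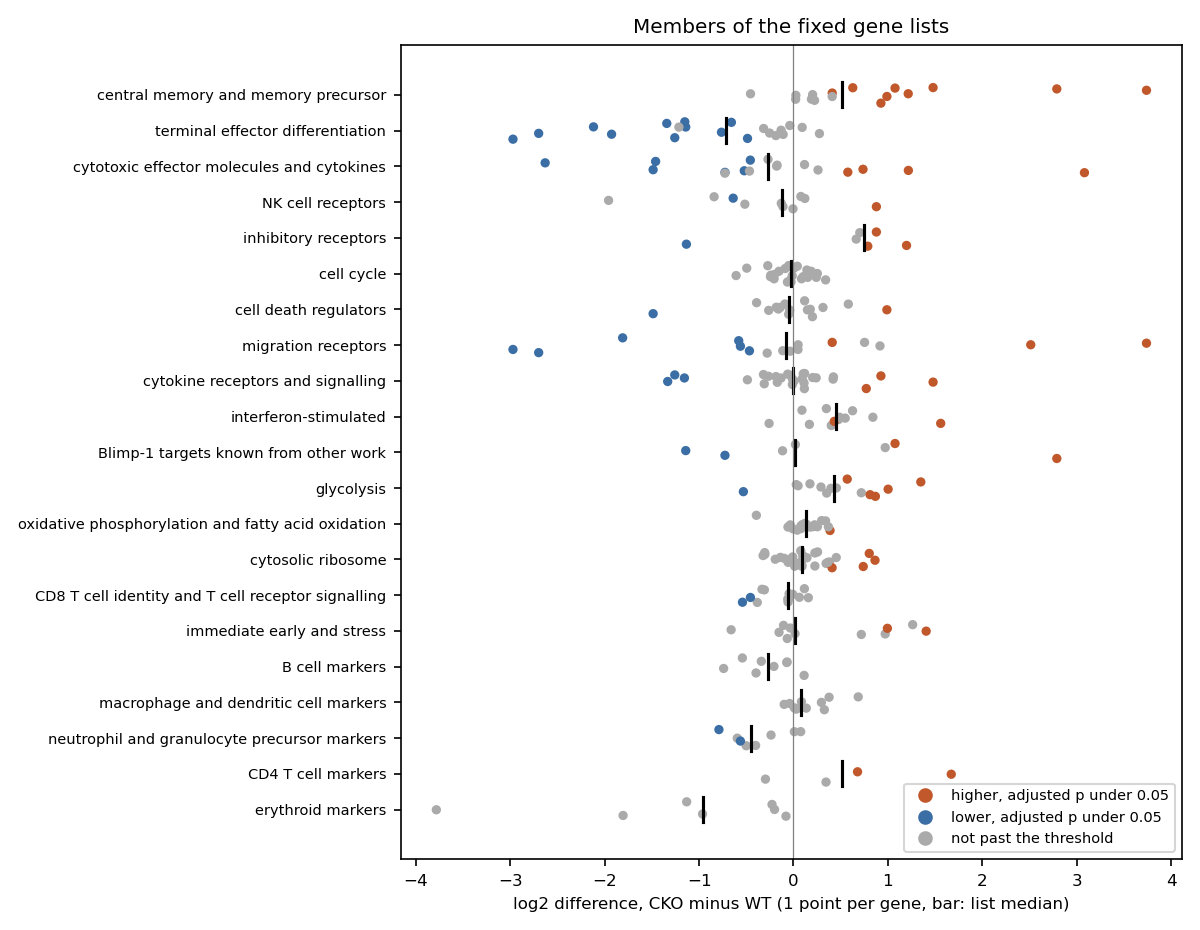
Log2 difference (CKO minus WT) of each measured member of the 21 gene lists, 1 point per gene, orange for higher and blue for lower past the threshold, with a black bar at the list median. Medians run from -0.96 for erythroid markers to 0.74 for inhibitory receptors.

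**Figure D5:**
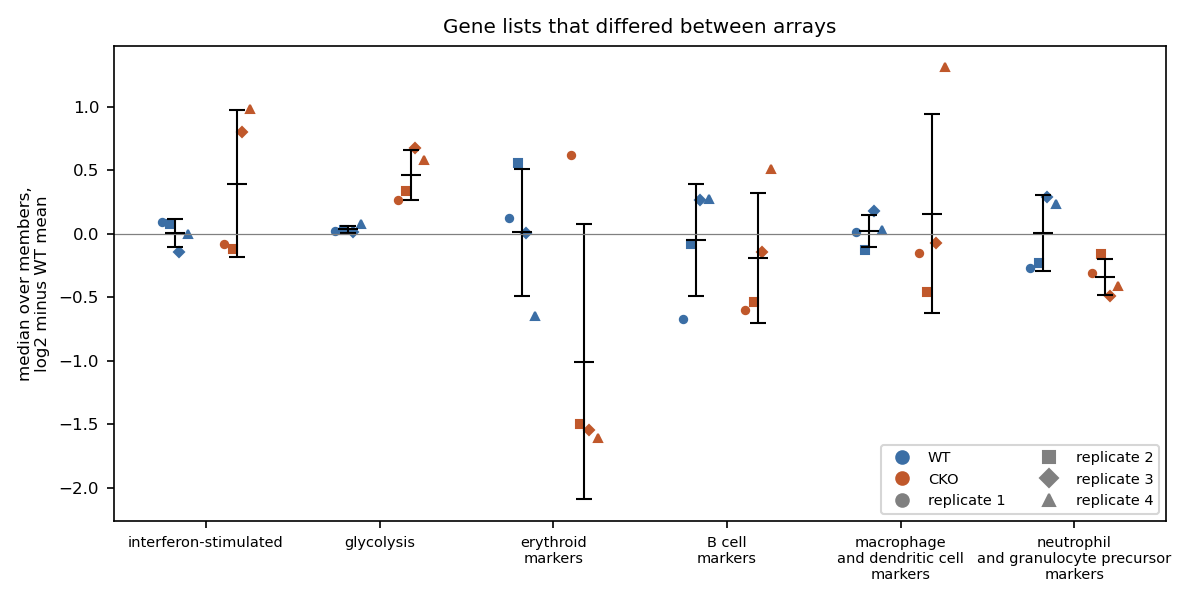
Median over list members of log2 signal minus the WT mean, for 6 lists in each array, with WT in blue, CKO in orange, a marker shape per replicate number and black bars for mean ± SD. Interferon-stimulated genes were at 0.80 and 0.98 in CKO3 and CKO4 only, and erythroid markers at 0.62 in CKO1 against -1.61 to -1.50 in the other CKO samples.

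By fry, 8 of the 21 lists passed, against 11 by camera and 2 with an estimated correlation, which were the memory and the terminal effector list. Lists share members such as Ccr7, Cx3cr1, S1pr5, Bcl2, Fasl and Id3, so their results are not independent. With samples numbered 1 and 2 alone, 11 genes were higher and 8 lower, and with samples 3 and 4 alone 517 and 406. With samples 1 and 2 alone, 49 calls of named genes were lost, the Prdm1 probe that fell included.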

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

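Genes and lists were screened for samples far from the rest by rules fixed in advance, but the screening of single transcripts such as Alas2, Eif2s3y, Kdm5d, the 18S probe and the immunoglobulin probe was chosen after their values were seen. In 218 groups of 4 values, 12 had a sample far from the others by Dixon's test, or 5.50%, where chance gives about 5%.

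Among genes reported above, S1pr5 was at 8.35 in CKO1 against 6.90 in the next CKO sample, and Prf1 at 8.51 in WT2 against 9.70. Ltf was at 6.23 in CKO1 against 5.99, and Il21 at 6.96 in CKO3 against 6.45. The median of the central memory list was 0.0833 in WT1 against -0.0251 in the next WT sample. The red cell transcripts Slc4a1 and Alas2 stood at 8.47 and 8.43 in CKO1, against 6.25 and 6.12 in the next CKO sample, and the erythroid list median was 0.618 there against -1.50.

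The Y-linked gene Eif2s3y was at 10.5 in WT1 and 10.9 in CKO1, against 6.52 and 6.18 in the next samples of their groups. Kdm5d, also Y-linked, was at 8.33 in WT1 against 5.86, and at 8.11 in CKO1. The 18S ribosomal RNA probe was at 10.8 in CKO2 against 12.7 in the next CKO sample.

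The probe for the immunoglobulin mu constant region, which carries no gene name in the annotation, was higher in CKO by 1.16 log2 (SE 0.17, limma adjusted p = 0.00399), at 9.78 to 10.2 in the CKO samples and 8.27 to 9.02 in the WT samples. The kappa constant probe differed by -0.27 (SE 0.48, adjusted p = 0.816) and the gamma 2c constant probe by -1.38 (SE 0.60, adjusted p = 0.22).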

How the results depend on the processing

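Cyclic loess, leaving out both samples numbered 2, and the fits on samples 1 and 2 or 3 and 4 alone were chosen after the data were seen. The central memory and terminal effector lists kept direction and call in every setting run, with adjusted p up to 0.0122 and 0.0484, and so did the Prdm1 probe that rose. The Prdm1 probe that fell kept them except with samples 1 and 2 alone, at -1.18. Of 70 other named genes, 62 passed, and 14 of these kept their call in each setting that tested them, of at most 21. Of 1291 combinations of setting and called gene, 1147 kept the call, 144 lost it and 0 reversed; for genes without a call, 156 combinations stayed so and 10 gained one. Array signal over background limits dim genes, and repeated quantile normalization and median centring moved values by at most 0.0400 and 0.00152 log2, so they test little. Cyclic loess moved values by at most 0.0664.

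Genes higher and lower numbered 556 and 461 with the replicate block, 645 and 527 with array weights, 588 and 399 at an adjusted p under 0.1, 233 and 145 at 1.5-fold or more, and 11 and 8 with samples 1 and 2 alone; samples 3 and 4 alone gave 406 lower. Probes higher and lower numbered 749 and 611, 850 and 685, 754 and 522, 292 and 175, and 13 and 8 in those settings; 553 were lower with samples 3 and 4 alone, and 464 without both samples numbered 2. With 1 sample left out, genes higher ran from 189 to 419, genes lower from 102 to 341, probes higher from 242 to 559 and probes lower from 121 to 427. A stricter or looser threshold changes counts by construction. The number of samples does not account for the counts. Samples 3 and 4 alone gave 517 genes higher and 406 lower, against 11 and 8 with samples 1 and 2 and 383 and 246 with all samples. Without CKO2 the counts rose to 419 and 341. Within each group, the sample numbered 1 alone had bright Y-linked genes, and the sample numbered 2 had the lowest 18S ribosomal RNA signal. Why the counts depended on which samples were used was not tested, nor was the cause for the other settings.

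The block ended the call of the CD8 identity list (adjusted p = 0.0799) and the CD4 list (0.0546) and changed no other list. Without a filter the inhibitory receptor list (0.0672) and CD4 list (0.213) lost their call and cell death turned higher (0.947). With the upper quartile of probes the cytotoxic list passed (0.0474) and cytokine receptors turned lower (0.828). Adding 50 ended the CD4 (0.0708) and erythroid (0.0767) calls. Array weights ended the CD8 identity (0.0724) and erythroid (0.0701) calls and turned cell death (0.920). The mean of probes ended the CD8 identity call (0.0725), and cyclic loess those of ribosome (0.0575) and CD4 (0.0603).

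With an estimated correlation the lost calls were inhibitory receptors (0.373), interferon (0.469), glycolysis (0.305), oxidative phosphorylation (0.278), ribosome (0.273), CD8 identity (0.273), neutrophil (0.416), CD4 (0.305) and erythroid (0.486). By fry, inhibitory receptors (0.0766), interferon (0.193), neutrophil (0.0783) and erythroid (0.267) did not pass, Blimp-1 targets did (0.0120), and migration turned higher (0.0824).

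Without both samples numbered 2, cell cycle passed as lower (0.0169), cell death and cytokine receptors turned (0.798 each), and CD8 identity (0.103) and erythroid (0.270) were lost. Samples 1 and 2 alone gave cytotoxic 0.00562, natural killer receptors 0.0133, cell cycle turned higher 0.00562, interferon turned lower 0.330, Blimp-1 targets turned 0.998, macrophage turned 0.172, neutrophil lost 0.7498, CD4 lost 0.0773 and erythroid lost 0.172. Samples 3 and 4 alone gave cell cycle lower 0.000227, cell death turned 0.507, cytokine receptors turned 0.697, oxidative phosphorylation lost 0.252, ribosome lost 0.0843, CD8 identity lost 0.192, immediate early higher 0.0170 and macrophage higher 0.04996.

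With 1 sample left out, adjusted p ran from 0.0269 to 0.274 for the cytotoxic list, 0.0328 to 0.351 for natural killer receptors, 0.0433 to 0.938 for cell cycle, 0.621 to 0.969 for cell death, 0.628 to 0.969 for cytokine receptors, 0.000120 to 0.0881 for interferon, 0.0299 to 0.115 for CD8 identity, 0.0351 to 0.273 for immediate early, 0.0299 to 0.567 for B cells, 0.103 to 0.686 for macrophage, 0.00441 to 0.0925 for neutrophil, 0.0328 to 0.0919 for CD4 and 1.04e-05 to 0.194 for erythroid. Cell cycle turned without WT3, WT4, CKO1 or CKO4, cell death without CKO1 or CKO2, cytokine receptors without WT2 or CKO4, and macrophage without CKO4.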

Other observations

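The tests of linked alleles and of cell admixture below, and the joining of the symbol roots Tnfrsf and Tnfsf into 1 family and its extension to members with other symbols, were chosen after the results were seen. Among 79 gene families formed by symbol root, only this joined family, from the tumour necrosis factor superfamily, passed: 8 of 22 tested genes rose, 36.4% against 4.65% of other genes (Fisher's exact test, two-sided, p = 4.16e-06, Benjamini-Hochberg adjusted over 158 tests 0.000657). Besides Tnfrsf26 and Tnfrsf4, these were Tnfsf4, the ligand of OX40, at 1.53 log2 (adjusted p = 0.00117), Tnfrsf25 at 1.03 (0.00475), Tnfsf13b, the B cell survival factor BAFF, at 0.85 (0.0026), Tnfrsf22 at 0.72 (0.0132), Tnfrsf13c, a BAFF receptor, at 0.71 (0.0119), and Tnfsf11, which encodes RANKL, at 0.49 (0.045). Tnfrsf1a, a receptor for tumour necrosis factor, fell by 0.44 (0.0489). Of 8 tested members of the superfamily with other symbols, named by hand, Tnf at 0.74 (0.0179), Ltb at 0.71 (0.011) and Lta at 0.45 (0.0408) rose and Fasl at -1.49 (0.0017) fell, while Fas at 0.58 (0.124) and the others did not pass. With them 11 of 30 rose and 2 fell, 36.7% and 6.67% against 4.61% and 3.03% of other genes (Fisher's exact test, two-sided, unadjusted p = 5.59e-08 and 0.231). The 30 genes include the 8 whose rise had already been seen. Fisher's test takes genes as independent, and its p-values for both sets leave out that the sets were chosen late, so they only describe these genes.

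The 629 genes past the threshold were set against other divisions of the samples. Of the 35 splits into 4 and 4, 1 gave as many genes, the real one, and the highest other gave 1 gene. A share of 1 of 35 is the smallest this test can give. Among the 8 splits that part every pair of numbers, the real one gave 1017 genes with the block and the highest other 0. There the smallest possible share is 1 of 8, so with the numbers taken as pairs chance assignment cannot be excluded. Alleles carried along with the modified Prdm1 locus could also alter genes linked to it. A share of called genes among the 50 nearest tested genes, planned first, was not used, since 50 genes are too few to make up a large part of 629; 5 of these 50 passed, or 10%, against 7.74% elsewhere (Fisher's exact test, two-sided, p = 0.59). On the whole chromosome of Prdm1 lay 5.89% of the called genes (exact 95% interval 4.18% to 8.03%), where 62.7% would have been reached had all tested genes there been called. Of all tested genes, 4.87% lay there, and 9.39% of these were called against 7.68% elsewhere. Altered genes on that chromosome thus make up no more than 5.89% of the calls. A main share was hardly reachable, since it would have needed most tested genes there to be called, so the test decides little beyond that bound. It does not speak on single genes such as Prf1, which is among the 50, nor on effects of such alleles on genes elsewhere.

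The fall of terminal effector genes beside the rise of memory genes might come from CD8 T cells in the CKO samples that are not effector cells, although the sort for tetramers carrying viral peptides would remove most cells without that specificity. Dilution that lowers Klrg1 as measured needs 77% of such cells, and transcripts they lack would fall alike, here taken as -1.06 or below, the midpoint between 0 and the log2 change of Klrg1. For resting cells, taken to lack proliferation transcripts, this includes the cell cycle list. Its median was -0.0215, with a 95% interval over genes, not samples, of -0.15 to 0.10. Over the 24 of 26 members with WT means at least 2 log2 above the lowest value, the interval was -0.20 to 0.10. No member was below -0.61. Relative to the WT mean, the list median was -0.14 to 0.11 in CKO samples and -0.31 to 0.30 in WT samples. All these values lie above -1.06, which argues against resting cells as the whole cause. Cycling cells that are not effector cells cannot be told apart from an effect of the genotype by the cytotoxic list. Its median was -0.27 (95% interval over genes -0.73 to 0.26), but called members went both ways, from 3.08 for Xcl1 to -2.63 for Gzma. Such cycling cells stay open, as do a smaller share of resting cells, a changed mix of effector subsets and an effect of the genotype within cells. None of these was tested further.

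Why the Prdm1 probes moved in opposite directions was not tested, since probe positions and sequences were not used here.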
